A study of Mus musculus with 15 samples.

How the data were processed

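The authors deposited a table of FPKM with 23845 gene records and 15 libraries, and all 15 columns matched a sample, with 0 unmatched. Per the submitters' processing notes the reads were handled with CASAVA and FastQC, aligned to mm10 with TopHat2 2.0.3, Bowtie 0.12.8 and SAMtools 0.1.18, and quantified with Cufflinks 2.0.0. Per the labels the libraries came from a TruSeq RNA kit and 3 µg of RNA and were read on an Illumina HiSeq. No reads were aligned again here, and the depth of each library is unknown. One item is not reported here.

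Record positions carry mm10 coordinates, and 7658 starts matched a GENCODE M21 gene start after adding 1, against 771 without. Dates stood in place of 27 symbols, of which 21 passed the filter, and 754 records share a symbol with another record, of which 159 passed. Records that share a symbol were kept apart and are marked by locus.

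Records with at least 1 FPKM in at least 3 of the 15 libraries were kept, which left 13838. Values were taken as log2(FPKM + 1), which shrinks differences between low values. One linear model with a mean per tissue was fitted to all 15 libraries in limma 3.58.1 (R 4.3.3), with eBayes using trend and robust settings from statmod 1.5.0. P-values were adjusted by the Benjamini-Hochberg method per comparison. A record was called where the adjusted p was under 0.05 and the log2 difference was at least 1 in size. The 8 comparisons were each section against liver, the mean of the 4 sections against liver, and each section against the one before it. Differences among the 4 sections were tested with an F test and a range of section means of at least 1. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

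Gene lists were written from general knowledge of the genes: 9 xenobiotic, 7 physiology and 17 cell type marker lists. Some lists named after an enzyme family also took in companion genes, and all counts given for a list cover these. The UDP-glucuronosyltransferase list took in Ugp2 and Ugdh, and the sulfotransferase list Papss1 and Papss2. The glutathione S-transferase list took in Gclc, Gclm, Gss and Gsr, and the carboxylesterase list Pon1, Pon2 and Pon3. Lists were tested with camera at the preset correlation of 0.01, adjusted over all lists and comparisons, and again with the correlation estimated per list. Camera ranks a list against all other records of the comparison. A list called lower is thus lower than those records, and its own median can still be positive. Differences in sign between median, mean and camera direction are given for the xenobiotic and physiology lists and not for the marker lists. Counts of called members are also given adjusted over the list alone where these differ. The squamous epithelium list kept 0 members, and the Brunner gland and stomach list kept 2 and had no camera test.

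The comparisons, thresholds, lists, alternatives and the rule for naming genes were fixed before the data were examined. Genes named are the 4 largest called differences each way, the called member with the largest difference each way of each xenobiotic and physiology list, the called member with the largest difference of each marker list, a fixed list of 41 genes, and the 5 most abundant records of each tissue. The genes named by per-library values in the closing part and the same-symbol pairs were chosen after values were seen. The 5 added alternatives were chosen after seeing the data: leaving out jejunum 24 and ileum 24, leaving out isolated zeros, leaving out short RNAs, summing the records of a symbol, and summing with both libraries left out.

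The procedure was tested on simulated data with 200 of 13838 genes changed. For ileum against jejunum it recovered 97% of genes changed by a log2 of 1.5 and 99% of those changed by 3, with 4 false calls among 13638 unchanged genes. For duodenum against liver it recovered 94% and 99%, with 1 false call. The simulated noise was independent between libraries, with the same spread in every tissue, and only genes above a low level were changed. Structure shared among libraries, as between those of jejunum and ileum, was not simulated, so recovery in the real data can be lower.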

Results

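RNA was sequenced from the liver and from 4 sections of the intestine (duodenum, jejunum, ileum and large intestine) of male C57BL/6 wild-type mice aged 2 to 3 months, with 3 libraries per tissue and 15 in all. Libraries are named by tissue and by the number in their title, as in jejunum 24. The values were FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for 23845 gene records, of which 13838 reached 1 FPKM in at least 3 libraries and were tested. The labels do not say whether the 3 samples of a tissue came from separate animals, so the p-values measure the spread between these samples, which may be technical. Read counts could not be recovered from the values, so the depth of each library is unknown and no counting interval is given. The FPKM of a library summed to 527249 ± 8961 in liver, 481892 ± 53035 in duodenum, 527159 ± 19033 in jejunum, 534450 ± 1830 in ileum and 387456 ± 2751 in large intestine (mean ± SD, n = 3). Liver libraries had 10282 to 10360 records at 1 FPKM or more, and large intestine libraries 12874 to 12918.

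The most abundant transcripts differed by tissue. Liver was led by Alb, the plasma protein albumin, at 25890 ± 3228 FPKM, followed by Apoa2, Apoe, Serpina1e and Fabp1. The small intestine was led by Defa24, an antimicrobial alpha-defensin of Paneth cells, at 10330 ± 3415 FPKM in duodenum, 24470 ± 2237 in jejunum and 20980 ± 2243 in ileum. Apoa4, an apolipoprotein of chylomicrons, stood at 7817 ± 892 FPKM in duodenum. In large intestine Zg16, a goblet cell lectin, stood at 4571 ± 958 FPKM, Lypd8 at 3781 ± 386 and Guca2a, the hormone guanylin, at 2834 ± 814. The first principal component held 69.2% of the variance and separated liver from intestine, and the second held 20% and separated large intestine from the small intestine. On the third (3.8%), which ran from duodenum to ileum, jejunum 24 (score 39.24) lay beside ileum 27 (38.57), and ileum 24 (8.76) lay beside jejunum 27 (6.36). Counts for jejunum and ileum are therefore also given without these 2 libraries wherever that moved a count of calls by more than 1.5 times, a choice made after seeing the data.

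The study's title sets xenobiotic processing genes in sections of the intestine beside those in liver, so each such gene was assigned to the tissue with its highest mean. Of 266 xenobiotic genes that passed the filter, 135 had their highest mean FPKM in liver, 57 in duodenum, 8 in jejunum, 21 in ileum and 45 in large intestine. Liver held the highest mean for 41 of 62 cytochrome P450 genes of families 1 to 4 and 14 of 18 in the UDP-glucuronosyltransferase list. The same held for 14 of 25 in the list of carboxylesterases, epoxide hydrolases and flavin monooxygenases, and 13 of 26 in the glutathione S-transferase list. Counts of a list include its companion genes, such as Papss2 in the sulfotransferase list. Duodenum came next for P450 genes (12), for alcohol, aldehyde and carbonyl enzymes (14 of 46, against 22 in liver) and for glutathione S-transferases (8). Sulfotransferases were highest in duodenum (4 of 9) or large intestine (4), with 1 in liver. Transporters were also spread over several tissues. Of 39 uptake transporters 16 were highest in liver, 7 in ileum and 9 in large intestine, and of 21 efflux transporters 6 were highest in liver, 4 in ileum and 8 in large intestine. The count for liver was 162 with median-of-ratios scaling, 155 with quantile normalization and 127 when every library was rescaled to the same sum of FPKM.

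**Figure D1:**
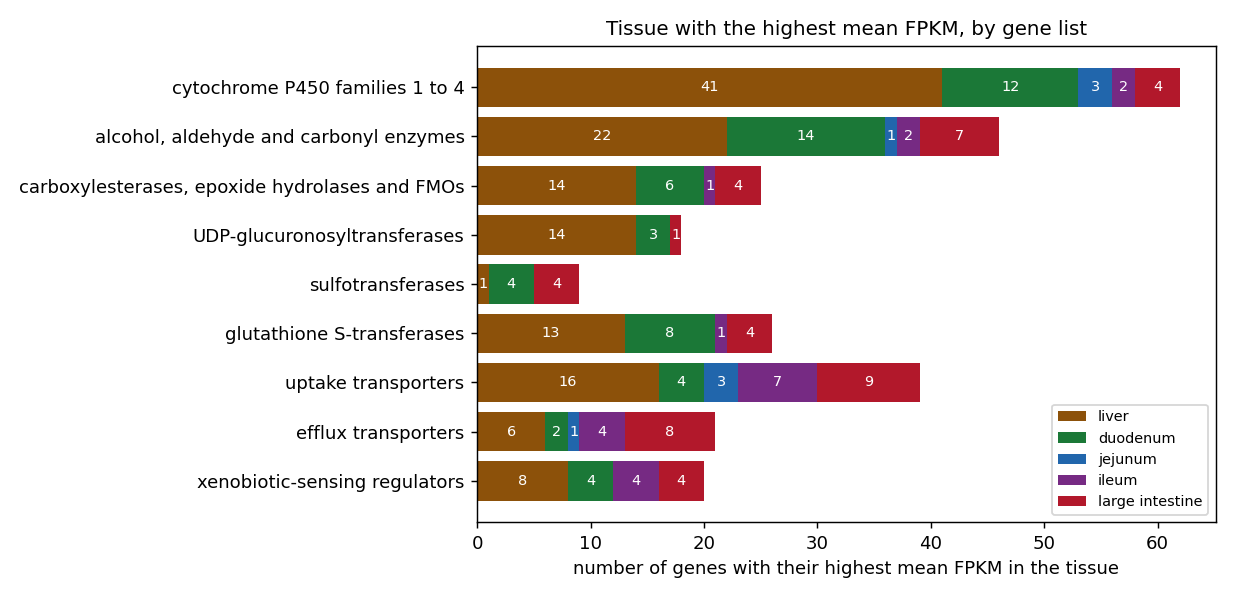
Number of genes of each xenobiotic list (horizontal axis) whose highest mean FPKM lay in liver, duodenum, jejunum, ileum or large intestine, with the number printed in each bar segment. Liver held 135 of the 266 genes with FPKM as deposited and 162 with median-of-ratios scaling.

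The mean of the 4 sections was also compared with liver. It averages sections that can differ from each other. Some genes of liver-secreted proteins were far lower in the sections: Alb differed by a log2 of -13.45 (SE 0.75, adjusted p = 8.03e-09), Mup7 by -12.31 and Mup3 by -12.21, the last 2 being major urinary proteins. Some goblet cell genes were far higher, with Zg16 at 4111 ± 878 FPKM in the 12 intestinal libraries and 1.90 ± 0.967 in liver (log2 difference 10.50, SE 0.20, adjusted p = 3.92e-15), Spink4 at 10.34 and Agr2 at 9.05. Bile acid synthesis was a liver program: 14 of its 15 genes were lower in the sections, including Cyp7a1, the rate-limiting enzyme at 15.6 ± 4.72 FPKM in liver, Cyp8b1 (-7.27, SE 0.09) and the bile acid ligase gene Slc27a5 (-8.03, SE 0.08).

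Among xenobiotic genes, 44 of 62 P450 genes were lower in the mean of the sections and 13 higher (camera adjusted p = 3.43e-20, and adjusted p = 0.101 with an estimated correlation). Cyp2f2 differed by -8.94, Cyp1a2 by -8.15, Cyp2e1, an ethanol-oxidising P450, by -8.04 and Cyp3a11, the main mouse Cyp3a drug-metabolising enzyme, by -4.74 (SE 0.72, adjusted p = 6.18e-05). Cyp2c65 (6.28), Cyp2c55 (3.85) and Cyp1a1 (2.86) were higher in the mean of the sections, which does not show that each section was higher. The sections averaged here were unlike each other for some genes, as given below for Cyp3a11. UDP-glucuronosyltransferases were lower for 14 of 18 genes, led by Ugt2b1 (-7.97), and higher for 1, Ugt1a7c (6.47; camera adjusted p = 3.24e-12, and adjusted p = 0.063 with an estimated correlation). Of the carboxylesterases, epoxide hydrolases and flavin monooxygenases 14 of 25 were lower, led by Ces3a (-9.16), and 5 were higher, among them Fmo4 (2.29) and Ces2e (2.29). Glutathione S-transferases divided into 11 lower, led by Gsta3 (-6.39) with Gstp1 at -3.21, and 5 higher, led by Mgst2 (7.75), with 10 not called. Sulfotransferases were mostly higher (6 of 9), Sult2b1 by 5.54 and Sult1b1 by 3.13, with Sult5a1 lower by a log2 of -3.23.

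Transporters went both ways in the mean of the sections. The basolateral hepatocyte uptake transporters Slco1b2 (-7.73) and Slc10a1 (-7.61) and the bile salt export pump Abcb11 (-7.07) were lower, while the peptide transporter Slc15a1 (5.81), the P-glycoprotein gene Abcb1a (4.86) and the bile acid exporter subunit Slc51a (5.83) were higher. The counts were 12 higher and 14 lower of 39 uptake transporters (14 and 14 after rescaling to the same sum) and 8 higher and 6 lower of 21 efflux transporters (6 and 6 with median-of-ratios scaling, 5 and 7 with quantile normalization). Of 20 xenobiotic-sensing regulators 4 were higher, led by the vitamin D receptor gene Vdr (6.49), and 7 lower, led by Nr0b2 (-4.57), with Ppara at -1.47. The pregnane X receptor gene Nr1i2 differed by 0.54 (adjusted p = 0.00046) and the aryl hydrocarbon receptor gene Ahr by -0.30 (adjusted p = 0.0261), both under the log2 difference of 1 needed for a call. The value of Nr1i2 also lay below the median of all records with FPKM as deposited (0.72). Over all records 6176 were called, 4937 higher and 1239 lower in the sections. The median log2 difference of all records was 0.72 with FPKM as deposited, 0.04 with median-of-ratios scaling and 0.01 with quantile normalization, and the calls were then 2650 higher and 2327 lower, or 2396 higher and 1992 lower. Camera, which ranks a list against all other records, placed the sulfotransferases (median 1.25, mean 1.08), efflux transporters (0.63, 0.39), bile acid handling (1.47, 1.64) and lipid absorption (0.59, 0.44) lower, against the sign of their medians, and called none of them.

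**Figure D2:**
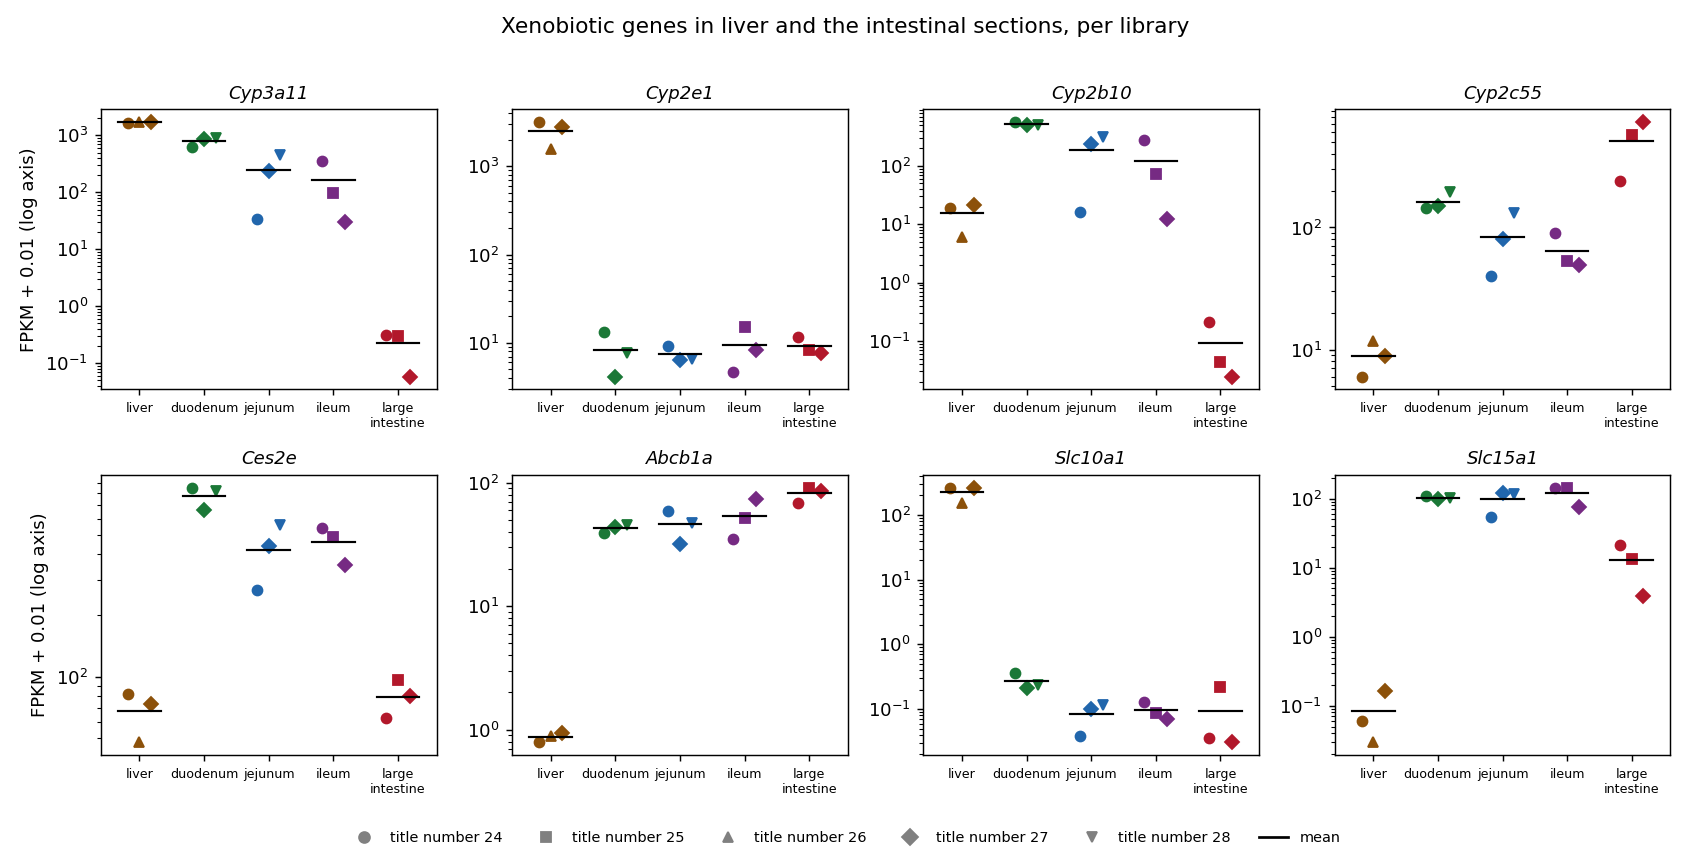
FPKM plus 0.01 on a log axis for 8 xenobiotic genes in the 5 tissues. Each point is 1 library, its shape gives the number in the library's title, and the line is the mean of 3 libraries; Cyp3a11 fell from a mean of 1686 FPKM in liver to 0.2145 in large intestine, and Cyp2c55 was highest in large intestine at 512.3.

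Duodenum against liver compared the first section of the gut with the liver. The drug-metabolising gene Cyp3a11 was 799 ± 159 FPKM against 1686 ± 24.7 in liver (log2 difference -1.10, adjusted p = 0.285), and Cyp3a13 was higher at 370 ± 51.5 against 47.0 ± 14.5 (2.98, SE 0.53, adjusted p = 0.000214). Cyp2b10, a phenobarbital-inducible P450, was 526 ± 33.4 FPKM against 15.6 ± 8.34 (5.15, SE 1.18, adjusted p = 0.00188), and Cyp1a1 was 49.5 ± 11.1 against 0.788 ± 0.339 (4.82). In all, 13 of 62 P450 genes were higher and 33 lower, the lower ones led by Cyp2f2 (-9.13), Cyp2e1 (-8.13) and Cyp1a2 (-7.94; camera adjusted p = 1e-13, and adjusted p = 0.173 with an estimated correlation).

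Conjugating enzymes of the duodenum were divided. Of 18 UDP-glucuronosyltransferases 12 were lower, such as Ugt2b1 (-7.89) and Ugt2b5 (-3.31), and Ugt1a7c was higher (7.32; camera adjusted p = 1.61e-08, and adjusted p = 0.111 with an estimated correlation). Of 9 sulfotransferases 5 were higher, among them Sult2b1 (6.32) and Sult1b1 (3.87), and 2 were lower, with Sult1a1 at -4.57. Of 26 glutathione S-transferases 8 were higher, including Mgst2 (8.22) and Gsta1 (5.06), and 7 lower, including Gsta3 (-6.11) and Gstp1 (-2.68); with median-of-ratios scaling the counts were 5 higher and 10 lower. Alcohol, aldehyde and carbonyl enzymes were higher for 14 of 46 genes, led by Adh6a (8.88), with the quinone reductase Nqo1 at 3.04, and lower for 14, led by Akr1c6 (-9.18). Carboxylesterases and their companions were higher for 8 of 25 genes, led by Ces2e (3.54), and lower for 11, led by Ces1c (-8.78). Efflux transporters were higher for 10 of 21 genes, among them Abcb1a (4.56) and Slc51a (6.69), and lower for 5, led by Abcb11 (-7.02); quantile normalization gave 6 higher and 6 lower.

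Absorption genes were also compared between duodenum and liver. Of 17 genes of sugar, peptide and amino acid absorption 16 were higher, led by sucrase-isomaltase, Sis, at 520 ± 58.5 FPKM against 0.124 ± 0.128 (8.86; camera adjusted p = 0.000889, and adjusted p = 0.376 with an estimated correlation). Of 16 lipid absorption genes 9 were higher, led by Apoa4 (7.56), and 1, Scarb1, was lower (-3.02; camera adjusted p = 0.999). Of 10 iron, calcium and vitamin uptake genes 8 were higher, led by Amn (5.82), and the iron exporter Slc40a1 was lower (-2.40; camera adjusted p = 0.0746). Cholesterol synthesis genes were lower for 9 of 16, led by Idi1 (-2.17; camera adjusted p = 1.2e-06, and adjusted p = 0.369 with an estimated correlation). Among cell type markers 15 of 15 hepatocyte markers and 7 of 7 Kupffer cell markers, such as Cd5l (-5.43), were lower, and 11 of 11 Paneth cell, 12 of 12 proliferation and 10 of 10 smooth muscle markers were higher. The comparison called 5507 records, 4233 higher and 1274 lower; median-of-ratios scaling gave 2557 and 2233, and quantile normalization 2314 and 1950. Among xenobiotic and physiology lists, medians, means and the camera direction differed in sign for alcohol, aldehyde and carbonyl enzymes (0.17, -0.30, lower), glutathione S-transferases (0.00, 0.26, lower), efflux transporters (0.83, 0.52, lower), regulators (-0.37, 0.02, lower) and bile acid handling (0.00, 0.71, lower). Camera called the alcohol, aldehyde and carbonyl enzymes, the glutathione S-transferases and the regulators, but none of them with quantile normalization (adjusted p = 0.211, 0.553 and 0.149).

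Jejunum against liver compared the middle of the small intestine with the liver. Paneth cell antimicrobials were far higher in jejunum than in liver, and Defa24 also led duodenum and ileum. In jejunum Defa24 reached 24470 ± 2237 FPKM against 2.20 ± 2.40 (log2 difference 13.23, SE 0.95, adjusted p = 7.87e-08). Defa21, listed at 0 in the 3 liver libraries, stood at 14310, 6782 and 1281 in jejunum. These alpha-defensin genes are near-identical copies, so the share of reads given to each is uncertain. All 11 Paneth cell markers, 10 of 11 goblet cell markers, led by Spink4 (10.52), and 7 of 7 stem cell markers, led by Olfm4 (8.38), were higher (camera adjusted p = 0.00385, 0.00999 and 0.0255, and adjusted p = 0.488, 0.357 and 0.376 with an estimated correlation). Enteroendocrine markers were higher for 13 of 14, led by Sst, somatostatin (5.98).

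Drug-metabolising genes of the jejunum lay further below liver in number than those of the duodenum, with 40 of 62 P450 genes lower and 13 higher (camera adjusted p = 3.68e-19, and adjusted p = 0.111 with an estimated correlation); the difference between these counts was not tested. Cyp3a11 was 244 ± 211 FPKM and lower than in liver (-3.41, SE 0.92, adjusted p = 0.00446), with 34.7 FPKM in jejunum 24, 242 in jejunum 27 and 457 in jejunum 28. Cyp2c29 was also lower (-5.82, SE 1.39), while Cyp2c65 (6.37), Cyp1a1 (3.13) and Cyp2c55 (2.99) were higher. Of the UDP-glucuronosyltransferases 13 of 18 were lower, led by Ugt2b1 (-8.02), with Ugt1a7c higher (6.25; camera adjusted p = 2.91e-12, and adjusted p = 0.063 with an estimated correlation). Carboxylesterases and their companions were lower for 15 of 25 genes, led by Ces3a (-9.37), and higher for 4, among them Fmo4 (3.08) and Ces2e (2.60; camera adjusted p = 1.51e-08, and adjusted p = 0.111 with an estimated correlation). Glutathione S-transferases were lower for 13 of 26, with Gsta3 at -6.52 and Gstm1 at -3.64, and higher for 5, led by Mgst2 (7.76; camera adjusted p = 8.53e-06, and adjusted p = 0.331 with an estimated correlation). Akr1c6, an aldo-keto reductase, was 727 ± 102 FPKM in liver and listed at 0 in the 3 jejunum libraries.

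Transport and absorption genes of the jejunum followed with Slc51a (7.11), Slc15a1 (6.44) and Abcb1a (4.61) higher and Abcb11 (-7.09) and Slc10a1 (-7.67) lower than in liver. The ileal bile acid binding protein gene Fabp6, listed at 0 in liver, stood at 6731 FPKM in jejunum 24, 23.1 in jejunum 27 and 5.61 in jejunum 28. Sugar, peptide and amino acid absorption genes were higher for 16 of 17, led by Sis (7.77), and the lipid absorption genes for 9 of 16, led by Mogat2 (6.84), with 5 lower (6 and 7 with median-of-ratios scaling). Jejunum against liver called 6331 records, 5087 higher and 1244 lower, or 2623 and 2414 with median-of-ratios scaling and 2376 and 2053 with quantile normalization. Among the xenobiotic and physiology lists medians, means and the camera direction differed in sign for sulfotransferases (1.12, 0.76, lower), efflux transporters (0.89, 0.66, lower), bile acid handling (1.93, 2.18, lower) and lipid absorption (1.14, 1.44, lower), none of which camera called.

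Ileum against liver compared the last section of the small intestine, where bile acids are reclaimed, with the liver. Of 7 bile acid handling genes 4 were higher in ileum, among them Slc51a at 251 ± 122 FPKM (7.75, SE 0.60, adjusted p = 1.59e-07), and Nr0b2 was lower (-4.49). Fabp6 and Fgf15, an ileal hormone that represses bile acid synthesis, were listed at 0 in the 3 liver libraries. In ileum 24, 25 and 27, Fabp6 stood at 256, 6597 and 8112 FPKM and Fgf15 at 7.77, 32.4 and 11.4. Bile acid synthesis genes were lower for 13 of 15, with Slc27a5 at -8.11 and Cyp8b1 at -7.30 (camera adjusted p = 2.93e-16, and adjusted p = 0.00501 with an estimated correlation), and Cyp7a1 was listed at 0 in the 3 ileum libraries.

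Of the P450 genes 42 of 62 were lower in ileum and 11 higher (camera adjusted p = 1.02e-18, and adjusted p = 0.111 with an estimated correlation). Cyp2f2 (-9.36), Cyp2e1 (-7.98) and Cyp3a11 (-4.02, SE 0.92, adjusted p = 0.00157) were lower, and Cyp2c65 (5.94), Cyp1a1 (3.59) and Cyp2c55 (2.72) higher. UDP-glucuronosyltransferases were lower for 14 of 18, with Ugt2b5 at -5.39 (camera adjusted p = 5.35e-12, and adjusted p = 0.063 with an estimated correlation), alcohol, aldehyde and carbonyl enzymes for 19 of 46 with 13 higher, and glutathione S-transferases for 14 of 26 with 6 higher, the latter led by Mgst2 (7.79). Sult2b1 (6.17), Sult1b1 (3.18) and Nqo1 (2.36) were higher. The cholesterol uptake gene Npc1l1 was higher (7.13), while the lipid absorption list as a whole held 8 higher and 5 lower of 16 genes, or 5 and 7 with median-of-ratios scaling. Colon-type ion transport genes were higher for 9 of 14, with Car4 at 5.93, and the water channel Aqp8 was lower (-5.14). Markers of goblet cells (10 of 11, with Zg16 at 10.77), enteroendocrine cells (13 of 14, with Nts, neurotensin, at 6.30) and T and NK cells (8 of 8, with Gzma at 4.09) were higher. Ileum against liver called 6036 records, 4750 higher and 1286 lower, or 2631 and 2398 with median-of-ratios scaling and 2389 and 2092 with quantile normalization. Camera placed sulfotransferases (median 0.92, mean 0.84), efflux transporters (0.95, 0.70), bile acid handling (3.94, 3.73) and lipid absorption (0.88, 1.30) lower, against the sign of their medians, and called none of these. It called uptake transporters (0.03, -0.49; adjusted p = 0.000194, and adjusted p = 0.219 with an estimated correlation) and regulators (0.00, 0.00; adjusted p = 0.0164, and adjusted p = 0.372 with an estimated correlation) lower than the other records. The median of all records was 0.675. Camera did not call the regulators with quantile normalization (adjusted p = 0.171) or the uptake transporters with median-of-ratios scaling (adjusted p = 0.0968).

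Large intestine against liver gave the most calls of the 4 sections. Much of the drug-metabolising set was lower there: Cyp3a11 was 0.215 ± 0.144 FPKM against 1686 ± 24.7 (log2 difference -10.45, SE 0.92, adjusted p = 4.78e-07), Cyp2c29 0.143 ± 0.21 against 1181 ± 82.5 (-10.03) and Cyp3a25 0.144 ± 0.0505 against 236 ± 3.11 (-7.70). Of 62 P450 genes 44 were lower and 8 higher, the higher ones led by Cyp2c55 at 512 ± 248 FPKM (5.60, SE 0.46, adjusted p = 1.6e-07), with Cyp2c65 at 5.03 (camera adjusted p = 1.33e-25, and adjusted p = 0.063 with an estimated correlation). Ces3a (-9.52), Akr1c6 (-9.40) and Ugt2b1 (-7.95) were lower, as was Ugt1a1 (-3.14), the bilirubin-conjugating enzyme. Carboxylesterases and their companions were lower for 15 of 25 genes and higher for 4, and alcohol, aldehyde and carbonyl enzymes lower for 23 of 46 and higher for 14, the latter led by Akr1b8 (4.24; camera adjusted p = 3.38e-10 and 5.1e-09, and adjusted p = 0.0848 and 0.111 with an estimated correlation). Sulfotransferases were higher for 7 of 9, among them Sult2b1 (3.79) and Sult1b1 (2.35).

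Among transporters, Abcb1a reached 81.9 ± 11.6 FPKM against 0.862 ± 0.0733 (5.47, SE 0.24, adjusted p = 1.18e-10), whereas the canalicular exporter Abcc2 was 0.414 ± 0.119 against 71.3 ± 6.07 (-5.68). The efflux list held 9 higher and 7 lower of 21 genes, or 6 and 8 with median-of-ratios scaling and 5 and 8 with quantile normalization. All 14 colon ion and water transport genes were higher, led by the carbonic anhydrase gene Car4 (8.03; camera adjusted p = 0.00563, and adjusted p = 0.112 with an estimated correlation). Lipid absorption genes were lower for 10 of 16, Fabp1 by -11.51, and higher for 3, led by Fabp2 (2.69; camera adjusted p = 1.53e-06, and adjusted p = 0.357 with an estimated correlation). The sugar, peptide and amino acid list was even, with 5 higher, led by Slc5a1 (4.28), and 5 lower, led by Slc2a2 (-5.47). Camera called this list lower, but not with a filter of 5 FPKM (adjusted p = 0.0548), median-of-ratios scaling (0.785) or quantile normalization (0.616). Lypd8 (11.01), Guca2a (10.94) and the goblet cell genes Agr2 (10.78) and Zg16 (10.67) were among the largest differences. All 10 smooth muscle markers, led by Actg2 (9.03), and all 11 enteric neuron and glia markers, led by Vip (4.67), were higher (camera adjusted p = 0.00254 and 0.0225, and adjusted p = 0.469 and 0.505 with an estimated correlation). Large intestine against liver called 7027 records, 5775 higher and 1252 lower. Median-of-ratios scaling gave 2814 and 2530 with 32 of the calls reversed in sign, quantile normalization 2650 and 2131 with 89 reversed, and rescaling to the same sum 8613 and 1107. Of the xenobiotic and physiology lists, median, mean and camera direction differed in sign for efflux transporters (0.09, -0.32, lower), regulators (0.02, -0.20, lower), bile acid handling (0.03, -0.06, lower), iron, calcium and vitamin uptake (0.49, 0.96, lower) and for sugar, peptide and amino acid absorption (-0.04, 0.12, lower).

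**Figure D3:**
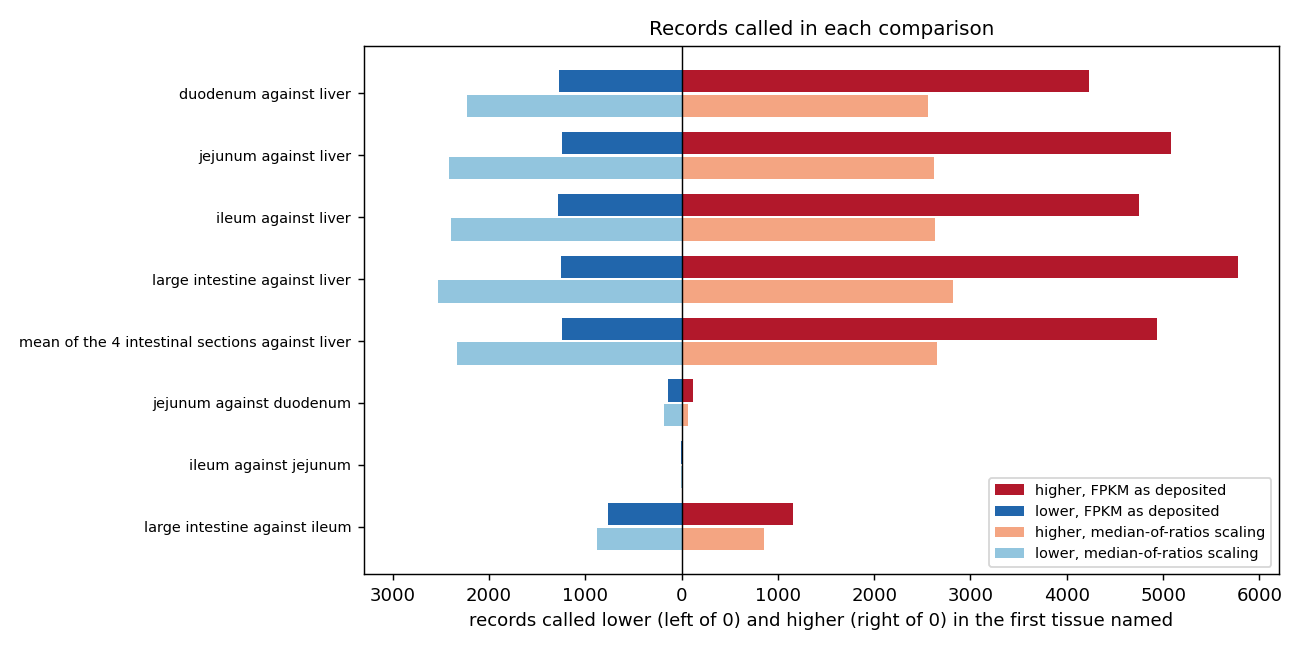
Number of records called higher (right of 0) and lower (left of 0) in the first tissue named, for the 8 comparisons, with FPKM as deposited (dark bars) and with median-of-ratios scaling (light bars). Against liver the mean of the 4 sections had 4937 higher and 1239 lower records as deposited, and 2650 and 2327 after scaling.

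Along the intestine, 2918 records differed among the 4 sections (limma F test, range of section means of at least 1 on the log2 scale). Of these 1762 had their highest mean in large intestine, 755 in duodenum, 289 in ileum and 112 in jejunum. Most xenobiotic enzyme lists peaked in duodenum: 27 of the 40 called P450 genes, 17 of 25 alcohol, aldehyde and carbonyl enzymes, 13 of 18 carboxylesterases and their companions, 10 of 12 UDP-glucuronosyltransferases and 11 of 14 glutathione S-transferases had their highest mean there. The 6 called sulfotransferases were divided between duodenum (3) and large intestine (3). Of 16 called lipid absorption genes 14 were highest in duodenum. The 17 called sugar, peptide and amino acid absorption genes peaked in duodenum (9) or ileum (8), and 5 of the 6 called bile acid handling genes peaked in ileum. All 12 called colon ion transport genes, all 9 called cholesterol synthesis genes and all 7 called goblet cell markers peaked in large intestine, and the 10 called Paneth cell markers in jejunum (6) or ileum (4). The 12 proliferation markers and the 9 B and plasma cell markers held 0 calls in this limma F test. Rescaling to the same sum raised the count to 4751.

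Jejunum against duodenum asked how the first 2 sections differ. Genes that fell included Papss2, which makes the sulfate donor, at 23.5 ± 5.80 FPKM in jejunum against 154 ± 55.6 in duodenum (log2 difference -2.63, SE 0.26, adjusted p = 0.000402), and Gsta4 at 46.4 ± 12.4 against 185 ± 71.6 (-1.93, SE 0.29, adjusted p = 0.00426). The alkaline phosphatase gene Akp3 (-4.61, adjusted p = 0.00835), Gm766 (-3.51) and the proton channel gene Otop3 (-3.19) fell further. The alpha-defensin gene Defa21 rose, with 14310, 6782 and 1281 FPKM in jejunum 24, 27 and 28 against 115 ± 63.7 in duodenum (5.59, SE 0.94, adjusted p = 0.00971), and the monocarboxylate transporter gene Slc5a8 rose from 0.308 ± 0.287 to 12.4 ± 9.34 (3.12, SE 0.44). With only the samples of these 2 sections in the fit Akp3 (adjusted p = 0.129), Gm766 (0.063), Gsta4 (0.0701), Defa21 (0.121) and Slc5a8 (0.123) were not called. Members of the xenobiotic enzyme lists fell: 8 of 62 P450 genes, 7 of 46 alcohol, aldehyde and carbonyl enzymes, 9 of 25 carboxylesterases and their companions, 6 of 18 UDP-glucuronosyltransferases and 9 of 26 glutathione S-transferases were called lower and none higher. Adjusted over the list alone, these counts were 9, 9, 10, 6 and 10. They depended on single libraries, and were 1, 4, 4, 2 and 1 without jejunum 24 and 0, 1, 3, 2 and 1 without duodenum 28. The camera adjusted p of the 5 lists were 4.29e-13, 1.05e-10, 2.58e-09, 1.35e-09 and 8.77e-12, and the adjusted p with an estimated correlation 0.184, 0.0857, 0.101, 0.101 and 0.148.

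Cell type and transporter lists were also compared between duodenum and jejunum. Paneth cell markers were higher for 6 of 11 genes, or 7 adjusted over the list alone (camera adjusted p = 0.000334, and adjusted p = 0.403 with an estimated correlation), and uptake and efflux transporters had 0 calls of 39 and 21 in limma. Camera also called pancreatic acinar (median -1.07, adjusted p = 0.0257), enteroendocrine (-0.39, 0.0108), erythroid (-0.96, 0.0334), T and NK cell (-0.66, 0.000233) and hepatocyte markers (-0.43, 0.000142) lower and enteric neuron and glia markers (0.34, 0.0382) higher. With an estimated correlation their adjusted p were 0.55, 0.272, 0.477, 0.262, 0.252 and 0.551, and without duodenum 28 the pancreatic acinar list had a median of 0 (adjusted p = 0.801). The enteric neuron and glia call also ended without duodenum 27 (camera adjusted p = 0.194), duodenum 28 (0.0521) or jejunum 28 (0.118). The erythroid call ended without duodenum 24 (0.0824), duodenum 27 (0.0558) or jejunum 28 (0.0724), and the enteroendocrine call with quantile normalization (0.122). The lists of lipid absorption (-0.75, adjusted p = 1.13e-06), sugar, peptide and amino acid absorption (-0.47, 0.000226), iron, calcium and vitamin uptake (-0.26, 0.00945) and bile acid synthesis (-0.11, 0.0177) were called lower, with 0.357, 0.357, 0.111 and 0.279 with an estimated correlation. The bile acid synthesis call ended with a filter of 5 FPKM (camera adjusted p = 0.0771), median-of-ratios scaling (0.115) or quantile normalization (0.0646). It also ended after rescaling to the same sum (0.0881). The iron list lost its call with that filter (0.106) or quantile normalization (0.0781), and the sugar list with quantile normalization (0.131). Cyp3a11 (-2.32, adjusted p = 0.0808), Cyp2b10 (-2.28, adjusted p = 0.161) and Cyp2c29 (-3.41, adjusted p = 0.0899) were not called; their means in jejunum were 244 ± 211, 190 ± 155 and 40.9 ± 37.7 FPKM, with the lowest value of each in jejunum 24. Cyp1a1 fell (-1.68, adjusted p = 0.0153), but the call ended without jejunum 24 (-1.41, adjusted p = 0.0731) and without duodenum 28 (-1.82, adjusted p = 0.0572). Defa22 likewise rose by 5.60 (adjusted p = 0.0112), with adjusted p = 0.0534 without jejunum 24 and 0.053 without duodenum 28. Jejunum against duodenum called 251 records, 114 higher and 137 lower, or 65 and 181 with median-of-ratios scaling, 69 and 115 with quantile normalization and 87 and 177 after rescaling to the same sum. Single libraries moved the count: 67 were called without jejunum 24, 72 without duodenum 28, 167 without duodenum 24, 476 without jejunum 28, 32 with only the samples of these 2 sections in the fit, and 103 (40 higher, 63 lower) without both jejunum 24 and ileum 24.

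Ileum against jejunum called 16 records, 8 higher and 8 lower, none of them in a xenobiotic or marker list. All 16 belong to 10 symbols that the table lists at several positions, and most are pairs in which 1 record was near 0 where the other was high. Gm8989 on mm10 chromosome 7 from 106322396 to 106324528 was 161 ± 30.0 FPKM in jejunum and 2.64e-06 ± 6.16e-07 in ileum, while Gm8989 (locus 2) from 106075732 to 106077864 was 2.29e-06 ± 1.32e-06 in jejunum and 113 ± 25.6 in ileum. Gm5512, Syne1 and Mecom behaved likewise. With the records of a symbol summed to 1 value, limma called 0 records, with 927 at an unadjusted p under 0.05, and the summed Gm8989 differed by -0.52 (adjusted p = 0.755). Camera called 10 lists, of which 9 lost the call with an estimated correlation. Among these were bile acid handling, higher in ileum (median 0.89, adjusted p = 1.09e-05, and adjusted p = 0.151 with an estimated correlation), cholesterol synthesis (0.27, adjusted p = 6.66e-07, and 0.357 with an estimated correlation) and smooth muscle, lower in ileum (-0.46, adjusted p = 2.27e-05, and adjusted p = 0.336 with an estimated correlation). The others were regulators, iron, calcium and vitamin uptake, sugar, peptide and amino acid absorption and goblet cells, higher in ileum, and stem cells, proliferation and enteric neurons and glia, lower. The iron list had adjusted p = 0.000466 and 0.0492 with an estimated correlation, but 0.0589 without jejunum 24. Without both jejunum 24 and ileum 24 the iron list (adjusted p = 0.285), regulators (0.486), stem cells (0.207) and proliferation (0.138) were not called, and the sugar, peptide and amino acid list was called lower (median -0.21, adjusted p = 0.0081). Other lists called lower there and not with all libraries were P450 genes (adjusted p = 6.02e-09), alcohol, aldehyde and carbonyl enzymes (0.00817), glutathione S-transferases (1.26e-09), lipid absorption (7.6e-08), enteroendocrine cells (0.0164), T and NK cells (0.0373), carboxylesterases and their companions and UDP-glucuronosyltransferases. B and plasma cells (0.0132) and adipocytes (0.0113) were called higher. Leaving out these 2 libraries, which lay nearer the other section, favours a separation of ileum from jejunum. All list values without both libraries come from camera at the preset correlation alone. With all libraries, over all comparisons, 122 of 140 calls at that correlation were lost once it was estimated.

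The spread within jejunum and within ileum was wide for the genes graded along the gut. Fabp6 differed by 4.55 (SE 2.22, adjusted p = 0.731), with 6731, 23.1 and 5.61 FPKM in jejunum 24, 27 and 28 and 256, 6597 and 8112 in ileum 24, 25 and 27. The ileal bile acid transporter gene Slc10a2 (mm10 chromosome 8, 5085623 to 5105232) was 37.0, 0.591 and 0.129 FPKM in the same jejunum libraries and 1.86, 21.9 and 57.9 in the ileum libraries (1.94, adjusted p = 0.806). Cyp3a11 (mm10 chromosome 5, 145854607 to 145879854) went the other way, at 34.7, 242 and 457 in jejunum and 361, 98.9 and 29.9 in ileum. Without jejunum 24 and ileum 24, which leaves 2 libraries per section and was chosen after the libraries' correlations were seen, 217 records were called, 96 higher and 121 lower. Then Fabp6 (9.18, adjusted p = 0.000769), Slc10a2 (4.78, adjusted p = 0.0122), Fgf15 (3.23, adjusted p = 0.0122) and the bile acid receptor gene Nr1h4 (1.46, adjusted p = 0.00173) were higher in ileum. Cyp2c29 (-4.49, adjusted p = 0.00153), Cyp3a11 (-2.58, adjusted p = 0.0119), Cyp3a25 (-1.65, adjusted p = 0.00806) and Gstm1 (-2.13, adjusted p = 0.000651) were lower. In that setting 10 of the P450 genes and 8 of the glutathione S-transferases were lower and none higher, and 5 of 7 bile acid handling genes were higher. The 2 libraries left out were those lying nearer the other section, so this setting favours a separation of ileum from jejunum. Its adjusted p may thus be too small and are given as description.

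**Figure D4:**
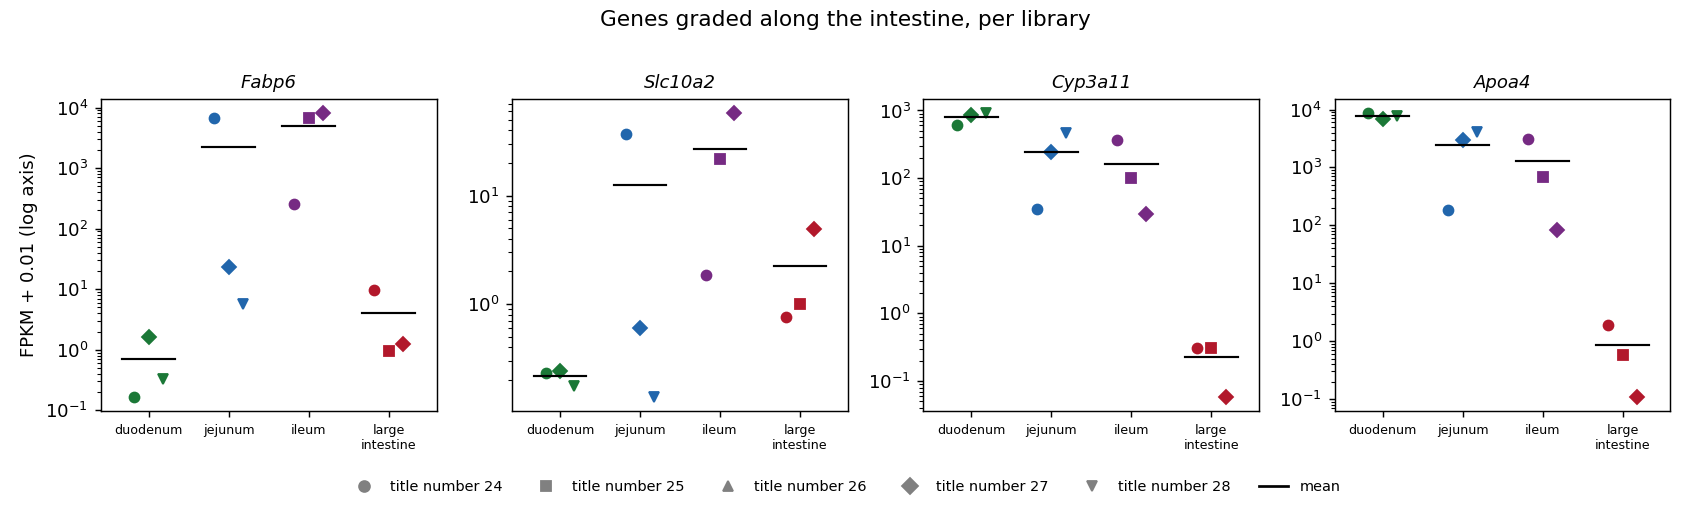
FPKM plus 0.01 on a log axis for Fabp6, Slc10a2, Cyp3a11 and Apoa4 in the 4 intestinal sections; each point is 1 library, shaped by the number in its title, and the line is the mean of 3. Jejunum 24 lies with ileum 25 and 27 (Fabp6 at 6731 beside 6597 and 8112 FPKM), and ileum 24 lies nearer jejunum 27 and 28 for Cyp3a11 and Apoa4.

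Large intestine against ileum compared the sections on either side of the junction between small and large bowel. The carbonic anhydrase gene Car1 rose from 0.485 ± 0.742 to 1303 ± 835 FPKM (log2 difference 9.63, SE 0.45, adjusted p = 9.84e-09), Retnlb, a goblet cell antimicrobial, rose by 7.97, and Saa1 (7.61) and Sycn (7.41) rose as well. Defa24 fell from 20980 ± 2243 to 8.79 ± 13.7 FPKM (-12.29, SE 0.95, adjusted p = 1.11e-06), and 10 of 11 Paneth cell markers fell with it (camera adjusted p = 4.03e-14, and adjusted p = 0.111 with an estimated correlation). Absorption genes fell almost as a block: 16 of 17 of the sugar, peptide and amino acid list (17 adjusted over the list alone), led by the aminopeptidase gene Anpep (-7.98), and 15 of 16 of the lipid list, led by Apoa1 (-9.97), with Scarb1 rising (1.30). Their camera adjusted p were 7.57e-18 and 2.58e-12, and the adjusted p with an estimated correlation 0.056 and 0.211. Colon ion and water transport genes rose for 11 of 14 (camera adjusted p = 4.09e-06, and adjusted p = 0.0288 with an estimated correlation).

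Xenobiotic genes both rose and fell between ileum and large intestine. Of 62 P450 genes 17 fell, among them Cyp3a11 (-6.42), Cyp3a25 (-6.30) and Cyp2b10 (-5.92), and 8 rose, led by Cyp2d34 (5.36), with Cyp2c55 at 2.88; adjusted over the list alone 18 fell and 9 rose (camera adjusted p = 0.000502, and adjusted p = 0.477 with an estimated correlation). Sult1a1 rose from 3.87 ± 0.773 to 160 ± 16.1 FPKM (5.05, SE 0.18) while Sult2b1 fell by 2.38 on the log2 scale, and Ugt1a6a rose (2.98) while Ugt2a3 (-3.75) and Ugt1a1 (-2.44) fell. Fmo4 (-3.11) and Ces2e (-2.52) fell and Ephx4 rose (2.71). Alcohol, aldehyde and carbonyl enzymes held 6 higher, led by Cbr2 (3.25), and 14 lower (15 adjusted over the list alone), led by Adh6a (-5.61), but 12 and 11 after rescaling to the same sum. Among transporters Slc51a (-5.98), Abcc2 (-4.65), Slc28a1 (-4.22) and Slc15a1 (-3.34) fell and Abcc3 rose (1.60). Of the uptake list 9 of 39 were lower and none higher, and of the efflux list 6 of 21 were lower and 2 higher (6 and 6 after rescaling to the same sum), with a median of 0.02 and a mean of -1.02. Pparg rose (2.71). Among cell type markers, smooth muscle rose for 9 of 10, led by Actg2 (2.60; camera adjusted p = 0.000205, and adjusted p = 0.376 with an estimated correlation), goblet cell markers for 6 of 11, while T and NK cell markers fell for 6 of 8, led by Gzma (-4.41; camera adjusted p = 2.25e-05, and adjusted p = 0.198 with an estimated correlation). The stem cell marker Olfm4 fell from 310 ± 44.0 FPKM in ileum by a log2 difference of -8.03, but only 3 of 7 stem cell markers were called in the limma F test among sections. Large intestine against ileum called 1915 records, 1153 of them higher and the rest lower, against 859 higher and 874 lower with median-of-ratios scaling and 2875 and 607 after rescaling to the same sum, which moved the median of all records from 0.14 to 0.59.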

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

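For named genes over all alternatives, the call status was the same for 14912 values, stronger (a call gained) for 208, weaker (a call lost) for 300 and reversed for 1. The same means that neither fit called the gene, or that both called it with the same sign, whatever the size of the difference. For the camera test of the lists the counts were 4766, 161, 247 and 17. Reversed means the opposite sign or camera direction and a call in 1 or both fits. Of 140 camera list calls, 122 were lost with an estimated correlation, which leaves the median as it was, and 18 kept.

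With adjusted p alone the calls were 11108 for duodenum, 11693 for jejunum, 11520 for ileum, 11854 for large intestine and 12171 for the mean of the 4 sections against liver, 3457 for jejunum against duodenum, 6623 for large intestine against ileum and 9121 for the differences among sections. Rescaling to the same sum of FPKM gave 3482 for large intestine against ileum and 4751 among sections, and treat gave 845 for large intestine against ileum.

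Jejunum against duodenum had 251 calls, but 462 with a pseudocount of 0.1, 453 with 0.01, 2 with treat, 32 with only the samples compared, 103 without jejunum 24 and ileum 24 and 100 when symbols were also summed. Leaving out 1 library gave 67 to 476. Ileum against jejunum had 16 calls, but 8 with a filter of 5 FPKM, 8 with treat, 0 with symbols summed, 217 without jejunum 24 and ileum 24 and 198 with both changes; leaving out 1 library gave 14 to 16.

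Leaving out 1 library gave 5442 to 5562 calls for duodenum, 5980 to 6634 for jejunum, 5968 to 6109 for ileum, 6937 to 7081 for large intestine and 6104 to 6261 for the mean of the sections against liver, 1825 to 2032 for large intestine against ileum and 2783 to 3167 among sections.

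List medians also changed sign where camera kept its direction and lost its call, and the cases given here are not all of them. Regulators had medians of -0.590 in ileum and -0.603 in large intestine against liver with quantile normalization (camera adjusted p = 0.171 and 0.101). Alcohol, aldehyde and carbonyl enzymes: duodenum against liver went from 0.165 to -0.578 with median-of-ratios scaling and -0.370 with quantile normalization, efflux transporters: large intestine against liver from 0.085 to -0.546 and -0.391, and uptake transporters: ileum against liver from 0.030 to -0.688 with median-of-ratios scaling. Mecom: ileum against jejunum went to -0.11 with symbols summed (adjusted p = 0.904). Leaving out 1 library moved the list medians of this comparison from -0.150 to 0.025 for P450 genes, -0.131 to 0.028 for carboxylesterases and their companions (0.014 without jejunum 28), -0.158 to 0.315 for sugar, peptide and amino acid absorption, -0.332 to 0.397 for lipid absorption and chylomicron assembly: ileum against jejunum, and -0.294 to 0.117 for T and NK cells. Without both libraries titled 24 the medians were -0.242 for P450 genes, -0.044 for alcohol, aldehyde and carbonyl enzymes, -0.206 for sugar, peptide and amino acid absorption, -0.502 for lipid absorption, -0.190 for enteroendocrine cells and -0.320 for T and NK cells. Summing symbols as well gave the same medians as leaving out both.

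The number in the titles was tried as a block (pairing). Its consensus correlation was -0.012, the random block changed no named call, the fixed block made 15 named values weaker and 4 stronger, and the fixed block gave 5672, 6630, 6083, 7056 and 6342 calls against liver, 215 for jejunum against duodenum, 16 for ileum against jejunum and 1890 for large intestine against ileum. Residuals of 22 library pairs with the same number had a median correlation of 0.003 (-0.477 to 0.14), and 68 other pairs -0.008 (-0.338 to 0.507).

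Xenobiotic genes with the highest mean in jejunum numbered 8, but 18 with no filter, 4 with a filter of 5 FPKM or quantile normalization, and 5 with the other scalings or without duodenum 28. Those with the highest mean in large intestine numbered 45, but 27 with median-of-ratios scaling.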

Other observations

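Some cell type markers not yet described were called singly. B and plasma cell markers were higher in the mean of the sections than in liver for 4 of 9 genes, led by Igj (7.13), and adipocyte markers for 7 of 7, led by Cfd (4.78), but camera called neither list (adjusted p = 0.778 and 0.217). Erythroid markers were lower for 5 of 5, led by Alas2 (-5.50; camera adjusted p = 0.00104, and adjusted p = 0.319 with an estimated correlation). In large intestine the enteroendocrine marker Insl5 rose over ileum (6.58). Clps led the 3 of 9 pancreatic acinar markers higher in duodenum than in liver (7.31), and camera did not call that list (adjusted p = 0.866).

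Single libraries stood apart for several genes. Gkn3, a stomach gene, was 16.9, 12.6 and 2071 FPKM in duodenum 24, 27 and 28. Mptx1 was 14600, 362 and 38.0 FPKM in large intestine 24, 25 and 27, Ang4 2155, 182 and 86.4, and Retnlb 1046, 136 and 157. Alb was 15.5, 0.504 and 12.2 FPKM in duodenum 24, 27 and 28. Cyp4f14 was listed at 0 in liver 26 against 110 and 89.2 FPKM in liver 24 and 27, and at 0 in jejunum 28 against 224 and 350 in jejunum 24 and 27. Such isolated zeros numbered 81 over the table, of which 8 were not short RNAs. Whether such a 0 means absent expression or a locus left without a value could not be told.

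Of the tests below, the one on abundant transcripts was chosen before the result was seen and all the others after it. The 16 records called between ileum and jejunum belong to 10 symbols, and in 10 of 10 the ratio between the records of a symbol split liver, duodenum and jejunum completely from ileum and large intestine. The symbols were picked for a call between jejunum and ileum, so only liver, duodenum and large intestine were free to fall otherwise. Of 10 pairs picked for separating liver and duodenum from large intestine, 10 had the ratio of large intestine in ileum 24 and 9 in ileum 25 and 27, and 10 that of liver and duodenum in each jejunum library. A separate processing run for the libraries of ileum and large intestine, giving reads to another record of the same symbol, would produce such a split. Such a run would coincide with tissue wherever ileum or large intestine was compared with liver or jejunum, and among the sections. Any effect of it on other records there cannot be told apart from tissue. Against a difference in expression, the largest summed difference was 0.52 in size (Gm8989, -0.52, SE 0.26, adjusted p = 0.755).

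Jejunum 24 lay nearer the ileum libraries for 92 of 100 graded records and ileum 24 nearer the jejunum libraries for 85 of 100. An exchange of the 2 samples before the values were computed could do this, but 85 fell short of the 90 set for it, so it stays open. An exchange of columns in the finished table is argued against, since jejunum 24 had the record ratio of liver and duodenum in 10 of 10 same-symbol pairs, which were picked from liver, duodenum and large intestine alone. The place along the gut at which the samples were cut could also do it: jejunum 24 had a median position of 1.11 between the other jejunum (0) and ileum (1) libraries, and ileum 24 one of 0.11. The groups were kept as labelled.

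Against liver 79.9% of the calls for the mean of the 4 sections were higher. A few abundant liver transcripts could lower the FPKM of all others. To test this, the 100 most abundant records of every library were left out (335 records). The rest were rescaled to the same sum. For the mean of the sections 73.9% of the calls were then higher, 3856 against 1359, with a median log2 difference of 0.518. Rescaling to the same sum with all records kept gave 84.3% and a median of 0.952. The share became 67.2% for duodenum, 75.8% for jejunum, 73.4% for ileum and 76.8% for large intestine. With all records kept and rescaled it was 81.3%, 81.9%, 80.1% and 88.6% in the same order. Leaving out the abundant records lowered the share in each comparison, but most calls were still higher, so the explanation stays open in part. With median-of-ratios scaling the share was 53.2%, so the share depends on the scaling, and the values here cannot settle which scaling is right.

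Regrouping the same libraries gave fewer calls than the real groups in all but 1 comparison. Each count of splits given here includes the real grouping itself. For groups of 3 against 3 the splits are too few for a share under 0.05: of 10 splits, only the real one reached the real count for duodenum (5507, highest other 0), jejunum (6331, 1), ileum (6036, 0) and large intestine against liver (7027, 1), for jejunum against duodenum (251, 27) and for large intestine against ileum (1915, 1). For ileum against jejunum 2 of 10 splits reached 16, and the other gave 289, with jejunum 24, ileum 25 and ileum 27 against jejunum 27, jejunum 28 and ileum 24, which points to a structure of the samples. For the mean of the sections against liver 1 of 100 splits reached 6176 (highest other 11), and for the differences among sections 1 of 100 reached 2918 (highest other 2309).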
